A study of Mus musculus with 6 samples.

How the data were processed

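Total RNA was sequenced from 6 libraries of cells sorted from muscle as pericytes, 3 from stimulated and 3 from sham mice. Libraries were made with a stranded total RNA kit for very low inputs, per the labels' protocols. Groups and replicate numbers were taken from the sample titles. The submitters' processing notes name bcl2fastq 2.17.1.14, Trimmomatic 0.36, Salmon 0.8.2, R 3.5.1, edgeR and the build GRCm38; their order and settings are not given in the sources used here.

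The authors deposited a gene table of estimated counts for 53715 genes and, per library, a transcript table whose columns are, per the file headers, TPM, estimated count, length and effective length for 135181 transcripts. The deposited gene counts sum in each library to the estimated counts of its transcripts. For the 14096 genes with a TPM above 0.1 in every library, the ratio of gene count to deposited TPM was compared across libraries. After each library was scaled by its median ratio, it was constant within 1% in 100% of them. The gene values thus follow TPM times a factor per gene and a factor per library, and are not sums of reads. In such values a few reads on a short transcript can weigh as much as many reads on a long one: fold changes from the table and from summed transcript counts differed by over 1 (log2) in 284 of 26276 genes. Identical small RNA genes split reads evenly, so single members of such families are uncertain; they are not named here.

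Estimated counts were rounded to whole numbers. Genes were kept by edgeR's filterByExpr with a minimum count of 10 and a minimum total of 15, which left 26559. Libraries were scaled by TMM. The test was edgeR's robust quasi-likelihood F test (edgeR 4.0.16, R 4.3.3) of stimulated against sham with no other term, with Benjamini-Hochberg adjustment at 0.05. The SE of a log2 fold change is its size divided by the square root of F. CPM values are scaled by TMM. The common biological coefficient of variation was 0.4. Exact permutation of 3 against 3 libraries cannot give a two-sided p below 0.1, so single values were not tested that way; the fits across all genes were repeated for all 10 splits of the libraries into 3 and 3.

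Gene lists for cell types, signalling, stress, matrix and RNA quality were fixed before the data were examined, as were the design and the alternatives given below unless stated otherwise. Lists with at least 5 tested members, 44 in all, were tested with camera (limma 3.58.1) on log2 CPM with a prior count of 2 and a preset correlation of 0.01, and again with estimated correlations and with fry. Members were also adjusted over the list alone.

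Genes were named by a rule fixed in advance: up to 10 per direction with the largest change past the threshold, filled to 5 by unadjusted p where fewer passed, with a mean log2 CPM of at least 1, groups that do not overlap and no clone-like symbol; up to 4 members per list by p; and the sort, mural and growth factor genes given in the text. Since no gene passed, the first part holds 5 genes per direction, all by unadjusted p. The text names a part of the list members. Flt1, Esam, Setd5, Aaed1, Ltf, Ighm, Cd79a, Gm15927 and B430305J03Rik were chosen after their values were seen. Coordinates come from GENCODE mouse release 21 (GRCm38), to which 99.8% of gene identifiers matched.

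The alternatives were DESeq2 1.42.0, limma voom, RLE size factors, no filter, a filter of 1 CPM in 3 libraries, each library left out, the replicate number as a block, counts summed from transcripts, a surrogate variable (sva 3.50.0), mitochondrial and ribosomal RNA genes left out, and a threshold of 0.1. Added after the data were examined were protein-coding genes only, edgeR's likelihood ratio test, the older form of its quasi-likelihood fit, the endothelial list score as a covariate, and leaving out each library for the counts adjusted over the list alone. DESeq2 gave no adjusted p for 6724 genes. Transcript usage was tested with limma's diffSplice on voom values. The tests were run on simulated counts with 200 changed genes, in 5 draws for genes and 3 for transcript usage. Camera called a raised list in 5 of 5 draws and 0 others. Each gene was drawn independently there, so this cannot show camera's false calls where list members correlate. The estimated correlation of the endothelial list, for example, was 0.91. Replicates were checked for duplicated libraries: the chi-square per gene between replicates was 30.4 to 112, far above sampling noise, so all 6 were counted.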

Results

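RNA was measured in cells sorted as pericytes, the mural cells that wrap capillaries, from the gastrocnemius-soleus muscles of 14-week-old male C57BL/6J mice. The gate took CD146-positive cells lacking the leukocyte antigen CD45 and the endothelial antigen CD31. In 3 mice the lower leg muscles had been driven electrically through 40 contractions (20 eccentric and 20 concentric) over about 10 minutes, 3 hours before tissue collection, and 3 sham mice had not been stimulated. Each library came from a separate animal according to the stated group sizes. The stimulated libraries held 18204991, 21004095 and 23709220 estimated reads and the sham libraries 20292341, 17520338 and 21825118. Mitochondrial ribosomal RNA took 8.84 to 11.99% of them. Protein-coding genes took 61.8, 62.8 and 64.1% in the stimulated and 65.6, 71.7 and 65.1% in the sham libraries, so that the groups did not overlap.

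The sort genes describe the material before any comparison. Mcam, which encodes CD146, stood at 36.4 ± 15.6 CPM (SD, n = 3) in stimulated and 69.3 ± 33.3 CPM (SD, n = 3) in sham libraries. The pericyte genes Pdgfrb and Cspg4 stood at 26.5 ± 15.8 and 7.12 ± 3.56 CPM (SD, n = 3) after stimulation and at 40.6 ± 17.8 and 12.4 ± 3.87 CPM (SD, n = 3) in sham. Ptprc, which encodes CD45, reached 1020 ± 24.5 CPM (SD, n = 3) after stimulation and 624 ± 373 CPM (SD, n = 3) in sham, and Pecam1, which encodes CD31, reached 463 ± 101 and 850 ± 386 CPM (SD, n = 3), so that both antigens excluded by the gate had more RNA than Mcam. Of 37 tested lymphocyte and endothelial markers, 33 lay above the median pericyte marker. The libraries thus held much RNA of leukocyte and endothelial genes, and a group difference need not lie within pericytes. Sham replicate 2 stood apart, with a mean lymphocyte marker level of 3.21 log2 CPM against 5.09 to 5.66 in the other 5 libraries and a mean endothelial marker level of 9 log2 CPM against 6.99 to 8.27. Other libraries were not uniform. Stimulated replicate 3 had the highest mean fibro-adipogenic (5.82 log2 CPM), satellite cell (3.45) and tenocyte (3.69) marker levels. Sham replicate 3 had the fewest detected genes (34697) and the shortest median effective length (623 bases).

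**Figure D1:**
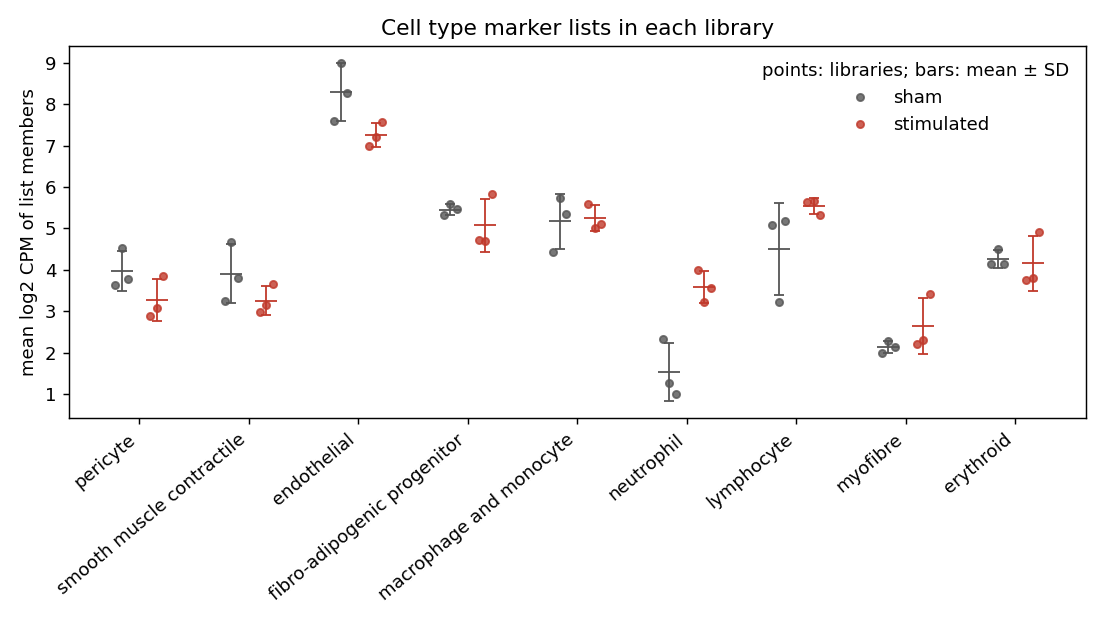
Mean log2 CPM of the members of 9 cell type marker lists (vertical axis) in each library, with sham in grey and stimulated in red; points are libraries and bars give the mean ± SD (n = 3). Neutrophil markers lie at 3.21 to 3.99 in the stimulated libraries and at 1 to 2.33 in sham, and endothelial markers at 6.99 to 7.58 and at 7.6 to 9.

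The comparison asks which transcripts of the sorted cells differ 3 hours after stimulation. No single gene passed the test, so 5 genes per direction are given first. They had the smallest p-values among genes that met the naming rule on level, overlap and symbol. Il1rn, the secreted antagonist of the interleukin-1 receptor (ENSMUSG00000026981.15, chromosome 2, 24336853 to 24351494, GRCm38), averaged 28.4 ± 4.87 CPM (SD, n = 3) after stimulation and 4.48 ± 0.591 CPM (SD, n = 3) in sham, a log2 fold change of 2.66 (SE 0.27). Acod1, which makes itaconate in activated macrophages (chromosome 14, 103046977 to 103056573), had a log2 fold change of 1.93 (SE 0.26), and S100a9, a calprotectin subunit abundant in neutrophils (chromosome 3, 90692632 to 90695721), one of 2.43 (SE 0.34). Kbtbd11 (chromosome 8, 15011025 to 15033333) had 1.81 (SE 0.23), and 1.13 when transcript reads were summed without length scaling. Greb1l (ENSMUSG00000042942.16, chromosome 18, 10325177 to 10562940) had 3.12 (SE 0.33) in the deposited gene table and -0.29 (SE 0.3) from summed transcript reads.

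Aplnr, the apelin receptor, was among the lower genes (ENSMUSG00000044338.9, chromosome 2, 85136225 to 85139923). It averaged 15.4 ± 2.19 CPM (SD, n = 3) after stimulation and 74.4 ± 34.3 CPM (SD, n = 3) in sham, a log2 fold change of -2.28 (SE 0.35). Efr3b (chromosome 12, 3962554 to 4038915) had -2.00 (SE 0.29), Arhgap18 (chromosome 10, 26753421 to 26918648) -1.61 (SE 0.27) and Samd5 (chromosome 10, 9622936 to 9675208) -1.72 (SE 0.29). Col28a1, a collagen (chromosome 6, 7997808 to 8192617), had -2.29 (SE 0.40), and -0.48 from summed transcript reads. The rule for naming these 10 genes required groups that do not overlap, which 12% of all tested genes had where chance gives 10%.

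The quasi-likelihood test of edgeR called 0 genes higher and 0 lower among 26559 at a Benjamini-Hochberg adjusted p of 0.05, the smallest adjusted p being 0.0504 for Il1rn, Greb1l and the predicted gene Gm15927. At an unadjusted p under 0.05 there were 1872 genes, 700 higher and 1172 lower, where 1328 would be met by chance on average. Splits that mixed the groups gave from 374 to 3126 such genes, so the 1872 cannot be read as an excess over chance. The count depended on the tool: limma voom also called 0 and 0, while DESeq2 called 74 higher and 153 lower. In counts simulated from these libraries the quasi-likelihood test recovered 47.8% of genes changed 4-fold and 2.4% of those changed 2-fold with 11 false calls among 61.2, and DESeq2 recovered 66.4% and 10.4% with 32.6 false calls among 109.4.

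Neutrophil markers were higher in the stimulated libraries. All 13 tested members were higher, with a median log2 fold change of 1.83; 12 of them passed when p was adjusted over the list alone and 0 when adjusted over all genes. S100a8, the partner of S100a9, averaged 21.3 ± 10.7 CPM (SD, n = 3) against 2.98 ± 0.937 CPM (SD, n = 3), and Trem1, a myeloid receptor, 9.74 ± 1.05 against 3.15 ± 0.278 CPM (SD, n = 3). The list passed camera with a preset correlation (adjusted p = 6.2e-15) but not with an estimated correlation (adjusted p = 0.29). The number passing over the list alone was 5 without stimulated replicate 1, stimulated replicate 3 or sham replicate 2, and 7 without stimulated replicate 2. In the same libraries the mean endothelial marker level was 7.26 log2 CPM against 8.29 in sham, and the mean lymphocyte marker level 5.53 against 4.5.

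Chemokine and cytokine genes were higher in 23 of 30, of which 9 passed when adjusted over the list alone, as did 1 lower gene, Cxcl12, and 0 over all genes. The 9 became 5 without stimulated replicate 2, and Cxcl12 did not pass without sham replicate 2, stimulated replicate 1 or stimulated replicate 2. Cxcl3, which attracts neutrophils, averaged 5.53 ± 0.764 against 0.629 ± 0.216 CPM (SD, n = 3), a log2 fold change of 3.13 (SE 0.40), and Ccl7 and Ccl2, which attract monocytes, had log2 fold changes of 2.08 (SE 0.34) and 1.27 (SE 0.27). Il1b had 1.52 (SE 0.33) and Lif, a growth factor for myoblasts, 1.27 (SE 0.32). Camera gave an adjusted p of 1.5e-06 with the preset and an adjusted p = 0.71 with an estimated correlation. The neutrophil markers, none of which is on this list, were higher in the same libraries, at 3.21 to 3.99 log2 CPM against 1 to 2.33, and endothelial markers lower, at 6.99 to 7.58 against 7.6 to 9. NF-kB response genes were higher in 16 of 22 members, 2 of them past the threshold over the list alone, Ccl2 and Tnfaip2 (log2 fold change 1.24, SE 0.31), with camera adjusted p = 0.011 and adjusted p = 0.71 with an estimated correlation. That list's camera call ended without sham replicate 1 (adjusted p = 0.11) and without stimulated replicate 2 (adjusted p = 0.058), and its 2 members became 0 without stimulated replicate 1, stimulated replicate 3 or sham replicate 1 and 1 without stimulated replicate 2.

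Metallothionein and glucocorticoid response genes were higher in 15 of 22, 6 of them past the threshold over the list alone and 0 over all genes. Fkbp5, a glucocorticoid-induced chaperone of the receptor, averaged 69.1 ± 23.2 against 18.2 ± 3.07 CPM (SD, n = 3), a log2 fold change of 1.92 (SE 0.30). Zbtb16, another glucocorticoid target, had 1.91 (SE 0.37), and the metal-binding proteins Mt1 and Mt2 had 1.61 (SE 0.36) and 2.63 (SE 0.60). Camera gave an adjusted p of 0.00093 and, with an estimated correlation, an adjusted p = 0.71; without sham replicate 1 it gave an adjusted p of 0.096. In the same libraries the mean endothelial marker level was 7.26 log2 CPM against 8.29 in sham, and the mean neutrophil marker level 3.58 against 1.53. Hmox1, the haem oxygenase of the oxidative stress list, averaged 137 ± 23.7 against 39.4 ± 20 CPM (SD, n = 3) and was the 1 member of 25 that passed over its list alone, while that list did not pass camera (adjusted p = 0.43); it was 0 without stimulated replicate 2, sham replicate 1 or sham replicate 3.

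Endothelial markers were lower in all 20 tested members, with a median log2 fold change of -1.08; 11 passed over the list alone and 0 over all genes. Kdr, the main VEGF receptor (chromosome 5, 75932827 to 75978458), averaged 279 ± 60 against 1150 ± 560 CPM (SD, n = 3), a log2 fold change of -2.04 (SE 0.40), and Emcn, a sialomucin of capillary endothelium, 33.9 ± 7.4 against 99.4 ± 32 CPM (SD, n = 3). Camera gave an adjusted p of 2.6e-13 and, with an estimated correlation, an adjusted p = 0.71. The number passing over the list alone was 2 without stimulated replicate 1, stimulated replicate 2 or sham replicate 2, and 20 without sham replicate 1. The median was -0.63 without sham replicate 2. In the same libraries the mean neutrophil marker level was 3.58 log2 CPM against 1.53 in sham, and the mean lymphocyte marker level 5.53 against 4.5.

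**Figure D2:**
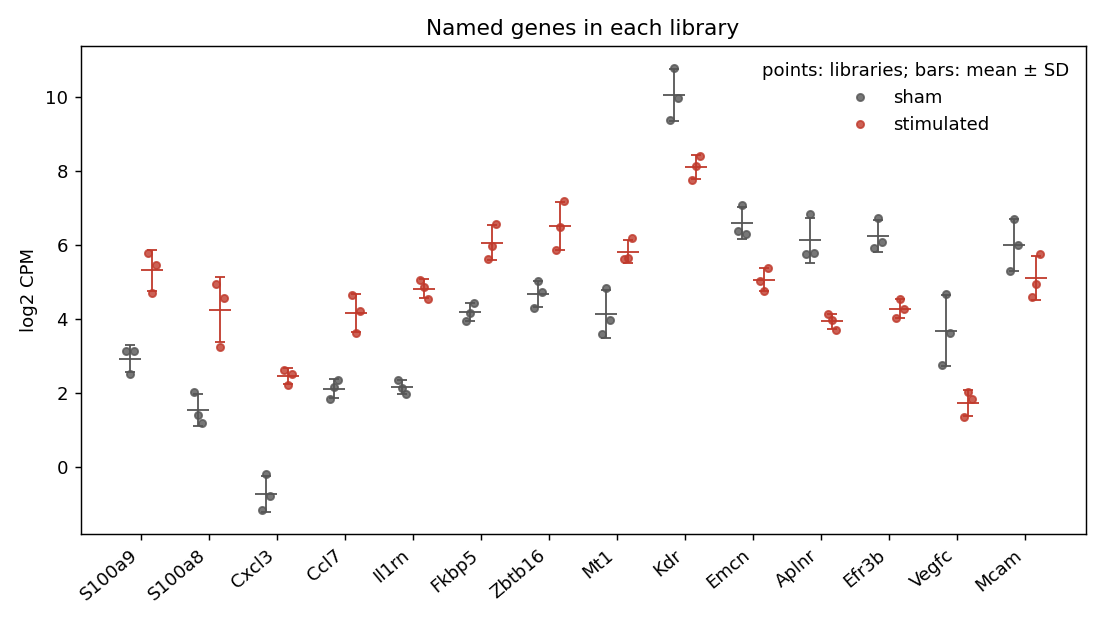
log2 CPM (vertical axis) of 14 named genes in each library, with sham in grey and stimulated in red; points are libraries and bars give the mean ± SD (n = 3). Il1rn, Cxcl3, Fkbp5, Kdr and Aplnr show groups that do not overlap, while those of Mcam do.

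Pericyte markers were lower in 17 of 19 and smooth muscle contractile genes in 17 of 18, with 0 members of either past the threshold over the list alone, but 8 pericyte markers without stimulated replicate 3, 1 without sham replicate 1 and 4 smooth muscle genes without sham replicate 1. The guanylate cyclase subunit Gucy1a1 had a log2 fold change of -1.32 (SE 0.42), Mcam -0.93 (SE 0.42) and the myosin light chain Myl9 -1.12 (SE 0.36). Camera gave adjusted p of 1.4e-05 and 5.3e-05, and adjusted p = 0.71 for both with an estimated correlation. Basement membrane genes were lower in 22 of 23 (camera adjusted p = 1.4e-05), with Agrn at -1.15 (SE 0.34), and fibrillar collagen and interstitial matrix genes in 25 of 29 (camera adjusted p = 0.00022), although Thbs1 of that list was higher at 1.19 (SE 0.34). Both had adjusted p = 0.71 with an estimated correlation, and the collagen list had a camera adjusted p of 0.11 without stimulated replicate 1. The endothelial markers were lower in the same libraries, at 6.99 to 7.58 log2 CPM against 7.6 to 9. With the endothelial list score as a covariate these 4 lists turned to mean log2 differences of 0.13, 0.43, 0.27 and 0.41. That score itself separated the groups, so these values cannot tell stimulation from the endothelial level.

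Growth factor genes were lower in 33 of 41 (camera adjusted p = 1.5e-06), 8 of them past the threshold over the list alone, and 0 over all genes. Fgf2, 1 of the 8, had a log2 fold change of -1.66 (SE 0.41) in the deposited gene table and 0.17 from summed transcript reads. The 8 became 0 without sham replicate 2, stimulated replicate 1 or stimulated replicate 2, 2 without stimulated replicate 3 and 4 without sham replicate 3. Vegfc, a lymphangiogenic factor, had a log2 fold change of -2.13 (SE 0.48) and Tgfb2 -1.54 (SE 0.36). Of the factors named in advance, Igf1 had -1.29 (SE 0.39), Hgf -0.43 (SE 0.40), Hbegf -0.21 (SE 0.36), Vegfa -0.01 (SE 0.23), Il6 0.32 (SE 0.47) and Pgf 0.50 (SE 0.60), and the progenitor marker Nes had -1.02 (SE 0.40). Growth factor receptor genes were lower in 22 of 30, with Kdr past the threshold over the list alone, and neurovascular and axon guidance genes in 20 of 26, with 5 past it, among them the netrin receptor Unc5b at -1.82 (SE 0.44). Kdr did not pass over the receptor list without stimulated replicate 1 or 2, and the receptor count was 2 without stimulated replicate 3 or sham replicate 3 and 3 without sham replicate 1. The 5 neurovascular genes became 8 without sham replicate 1 and 0 without any other library. These lists had camera adjusted p of 0.00088 and 0.00041, the first losing its call without stimulated replicate 1 (adjusted p = 0.059). With an estimated correlation the growth factor, receptor and neurovascular lists each had adjusted p = 0.71. Endothelial markers were lower in the same libraries by a mean score difference of -1.03, and with that score as a covariate these 3 lists turned to mean log2 differences of 0.05, 0.20 and 0.07. The score separated the groups and shares Kdr with the receptor list, so these values cannot tell stimulation from the endothelial level.

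Immediate early genes were lower in 22 of 28, with Atf3 at 90.9 ± 5.97 against 197 ± 64.2 CPM (SD, n = 3) and Fosb at 253 ± 54.2 against 569 ± 206 CPM (SD, n = 3), 0 of them past the threshold over the list alone, or 1 without sham replicate 1 or sham replicate 2 (camera adjusted p = 0.0085). Interferon response genes were lower in 25 of 29 (camera adjusted p = 0.00057), with Ifi44 at -1.40 (SE 0.41), and clock genes in 15 of 18 (camera adjusted p = 0.039), with the repressor Nr1d1 at -1.45 (SE 0.45). Each of these lists had adjusted p = 0.71 with an estimated correlation, and endothelial markers were lower in the same libraries, at 6.99 to 7.58 log2 CPM against 7.6 to 9. Without stimulated replicate 1 camera gave an adjusted p of 0.36 for immediate early and 0.55 for clock genes. Without sham replicate 3 it gave an adjusted p of 0.77, 0.17 and 0.32 for immediate early, interferon and clock genes, and without sham replicate 1 an adjusted p of 0.065 for clock genes.

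Ribosome and nucleolus biogenesis genes were higher in 24 of 25 (camera adjusted p = 3e-05), with Ppan at 0.92 (SE 0.25), and ribosomal protein genes in 29 of 30 by a median of 0.27 (camera adjusted p = 0.00037). Lymphocyte markers were higher in 15 of 17 (camera adjusted p = 3.5e-05), with the T cell gene Cd3e at 83.7 ± 3.31 against 26.5 ± 20.1 CPM (SD, n = 3). Myofibre genes were higher in 17 of 20 (camera adjusted p = 0.0071), with Ckm at 10.5 ± 8.85 against 3.56 ± 1.35 CPM (SD, n = 3) and a list mean of 3.42 log2 CPM in stimulated replicate 3 against 2 to 2.3 in the other 5 libraries. With an estimated correlation the adjusted p = 0.72 for ribosomal proteins and 0.71 for the other 3 lists. Without sham replicate 2, the library low in lymphocyte markers, the ribosomal protein list had adjusted p = 0.72 by camera, a median of -0.01 and 15 of 30 members higher, and the lymphocyte list had adjusted p = 0.0047. The ribosomal protein median was 0.74 without sham replicate 3. With the endothelial list score, which differed by -1.03, as a covariate the lymphocyte list turned to a mean log2 difference of -0.24. Since the score separated the groups, this value cannot tell stimulation from the endothelial level. The myofibre list had a camera adjusted p of 0.4 without stimulated replicate 3 and 0.054 without sham replicate 1.

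In all, 25 of 44 lists passed camera with the preset correlation, 9 higher and 16 lower, and 0 passed with an estimated correlation or by fry's directional test. The remaining lists that passed were proliferation genes (higher, adjusted p = 0.018) and, lower, ion channel and vasoregulation genes (adjusted p = 0.00013), markers of fibro-adipogenic progenitors (adjusted p = 0.011), SRF and YAP targets (adjusted p = 0.017), integrin and focal adhesion genes (adjusted p = 0.026) and Notch response genes (adjusted p = 0.043), each with 0 members past the threshold over the list alone. That count became 6 for fibro-adipogenic markers without stimulated replicate 3, and 1 for SRF and YAP without sham replicate 3, for integrin without stimulated replicate 2 and for ion channel genes without stimulated replicate 1. All of them except the ion channel list lost the call without 1 of at least 2 libraries: proliferation genes had adjusted p = 0.34 without sham replicate 2 and adjusted p = 0.065 without stimulated replicate 3. Without stimulated replicate 1 the adjusted p was 0.32 for fibro-adipogenic, 0.42 for SRF and YAP, 0.26 for integrin and 0.26 for Notch genes, and without sham replicate 3 it was 0.24, 0.3, 0.34 and 0.4. Without sham replicate 2 it was 0.15 for SRF and YAP, 0.34 for integrin and 0.44 for Notch genes, and without stimulated replicate 2 it was 0.17 for fibro-adipogenic and 0.069 for Notch genes. With an estimated correlation Notch genes had adjusted p = 0.72 and the other 5 lists adjusted p = 0.71. Endothelial markers were lower in the same libraries, with a mean score difference of -1.03. With that score as a covariate the ion channel, fibro-adipogenic, SRF and YAP, integrin and Notch lists turned to mean log2 differences of 0.06, 0.11, 0.32, 0.22 and 0.36. Since the score separated the groups, these values cannot tell stimulation from the endothelial level. The other 19 lists did not pass camera. Its adjusted p was 0.084 for tenocyte markers, 0.11 for nuclear respiratory chain and for matrix remodelling genes, 0.14 for mesenchymal progenitor markers, 0.17 for Wnt, 0.23 for TGF-beta and BMP and 0.29 for mitochondrially encoded genes. It was 0.43 for heat shock and for oxidative stress genes, 0.45 for erythroid and 0.58 for satellite cell markers, 0.63 for cholesterol synthesis and 0.64 for nuclear non-coding RNA. The adjusted p was 0.78 for Schwann cell, adipocyte and macrophage markers and for hypoxia, p53 and unfolded protein response genes. Leaving out a library gave calls to some of these lists: 7 without stimulated replicate 3, 5 without sham replicate 1, and 1 each without stimulated replicate 2, sham replicate 2 and sham replicate 3. Without stimulated replicate 3, tenocyte (adjusted p = 2.5e-06), satellite cell (0.0002), matrix remodelling (0.00036), Schwann cell (0.011), erythroid (0.015), Wnt (0.03) and mesenchymal progenitor genes (0.042) passed as lower, the tenocyte median being -1.21 and the satellite cell median -0.81. Without sham replicate 1, nuclear respiratory chain (adjusted p = 0.0014), matrix remodelling (0.0036), macrophage (0.015), oxidative stress (0.018) and TGF-beta and BMP genes (0.046) passed as lower. The macrophage list passed as higher without sham replicate 2 (adjusted p = 0.028), mitochondrially encoded genes without stimulated replicate 2 (adjusted p = 0.0066) and heat shock genes without sham replicate 3 (adjusted p = 0.041). For satellite cell, macrophage, hypoxia and p53 genes the median had the opposite sign to the test.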

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

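All tests of explanations in this part were chosen after the results were seen, as was the test of transcript usage.

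The deposited transcript tables, which the gene comparison does not use, held a difference in transcript usage between the groups in 2 genes, with 1 of the named transcripts above and 1 below its sham level. One Setd5 transcript averaged 28.5 ± 2.07 CPM (SD, n = 3) after stimulation and 2.27 ± 0.761 CPM (SD, n = 3) in sham, a log2 change of 3.80 relative to the gene's other transcripts (limma diffSplice, adjusted p = 1.4e-05). One Aaed1 transcript averaged 10.2 ± 3.14 and 28.4 ± 6.09 CPM (SD, n = 3), a relative log2 change of -1.84 (limma diffSplice, adjusted p = 0.037). On simulated counts this test found 16.7% of 200 genes with a 4-fold change in a transcript and made 15 false calls on average.

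Greb1l is higher in the deposited gene table by 3.12 (SE 0.33, log2) but not in reads. Its reads summed over transcripts gave a log2 fold change of -0.29 (SE 0.3). A transcript of 135 bases held a mean of 2.3 reads after stimulation and 0 in sham, yet its TPM of 0.967 ± 0.42 (SD, n = 3) exceeded those of all other Greb1l transcripts together. Length scaling of a few reads on a short transcript is a candidate explanation of the difference; a response of that short transcript itself stays open and was not tested.

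Neutrophil markers were higher after stimulation. A lower share of endothelial and mural cells would raise every other type alike. Whether it is the whole difference could not be decided. The neutrophil score minus the macrophage score differed by 1.98 (combined SD 1.34) and minus the fibro-adipogenic score by 2.42 (combined SD 1.12). For 7 of 9 other cell types the groups lay apart by more than that SD. All 9 differences use the same neutrophil score, which was picked after its own difference was seen. The 7 are therefore not independent, and that choice favours large differences. The groups overlapped against lymphocyte markers (difference 1.01, combined SD 1.21) and myofibre markers (1.54, 1.16). Without sham replicate 2 the macrophage difference of 1.57 lay within its combined SD of 1.6, while the lymphocyte difference of 1.52 exceeded its 1.1 without overlap. A lower share as the whole or a part of the difference therefore stays open. The members' deviations within groups had a mean pairwise correlation of 0.15, narrowly above the 95th percentile of 0.12 in 1000 matched random lists. Group means were removed first, so this does not tell whether the stimulated libraries held more neutrophils, or more of their RNA. The CD45 gate was set to exclude such cells. Ptprc, which encodes CD45, nonetheless stood at 1020 ± 24.5 CPM after stimulation and 624 ± 373 CPM in sham (SD, n = 3). None of the 13 markers is on another list used here. S100a9 stood at 41.8 ± 14.6 and Ltf at 17.5 ± 5.57 CPM after stimulation beside 36.4 ± 15.6 CPM for Mcam (SD, n = 3). CD45 RNA was thus present in both groups. Whether the neutrophil difference reflects a response of the stimulated muscle or unequal carry-over in the sort was not tested.

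Endothelial markers were lower after stimulation. Without sham replicate 2 the score differed by -0.68 against a combined SD of 0.56, with the highest stimulated library at 7.58 and the lowest sham library at 7.6. All 20 members stayed lower, but only 2 passed over the list alone. With so narrow a gap and so few sham libraries left, sham replicate 2 as the sole source could not be decided on. The members' deviations within groups had a mean pairwise correlation of 0.91, above the 95th percentile of 0.33 in 1000 matched random lists. Group means were removed first, so this does not tell whether a lower share of endothelial cells or RNA contributes. After each library's list mean was taken off, 3 of the 20 members differed (limma, adjusted over the list): Kdr by -0.92, Esam by 0.54 and Flt1 by 0.41. This argues against an equal shift of all members as the whole difference. It cannot decide on a lower share, which need not shift members equally if other cells in the sort also express them. The CD31 gate would remove endothelial cells, yet Kdr stood at 279 ± 60 and 1150 ± 560 CPM (SD, n = 3), and a response of the cells to stimulation stays open and untested.

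The 6 libraries allow 10 splits into 3 and 3, too few for a share under 0.05. The real split gave 0 genes higher and 0 lower and the highest other split gave 1 in each direction; with a real count of 0 this comparison tests nothing. For the lists the real split gave 25 and the highest other 33, and 3 of the 10 splits gave at least 25. At an unadjusted p under 0.05 the real split gave 1872 genes, and the highest other, with stimulated replicate 1 and sham replicates 1 and 2 against the rest, gave 3126.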

How the results depend on the processing

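The alternatives with the protein-coding genes, the likelihood ratio test, the older quasi-likelihood fit and the endothelial covariate were chosen after seeing the data. The counts of 0 genes higher and 0 lower depended on the tool. DESeq2 called 74 and 153, edgeR without a filter 44 and 65, and edgeR's likelihood ratio test 58 and 95; DESeq2 and the unfiltered fit shared 103 of their 227 and 109 calls. In simulated counts the unfiltered fit made 58.6 false calls among 126.4. RLE size factors called 3 higher (Il1rn, Greb1l and Gm15927), as did a threshold of 0.1; protein-coding genes only called 2 (Il1rn and Greb1l), and summed transcript counts 1 (Il1rn). Leaving out each library gave 0 to 1 higher, the 1 being B430305J03Rik without stimulated replicate 3, and 0 to 0 lower. The remaining alternatives, limma voom, the stricter filter, the surrogate variable, the mitochondrial and ribosomal RNA genes left out, the older quasi-likelihood fit and the covariate, called 0 and 0. The cause was not tested.

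The count of 25 lists became 0 with an estimated correlation and with fry, and 16 with the endothelial covariate, 6 of them shared in direction with the 25. Leaving out each library gave 17 to 30. With the replicate block 24 lists and 0 and 0 genes passed, the circadian clock list losing its call (camera adjusted p = 0.051). The sources do not say that equal numbers pair animals. Deviations from the group mean correlated by 0.33, -0.21 and 0.02 between same-numbered libraries, which cannot settle whether they pair. The block changed no gene call.

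Directions turned with the endothelial covariate, which takes up part of the group difference by construction. Its score includes Pecam1 and receptor genes such as Kdr. The values became 0.32 for Mcam, -0.35 for Ptprc, 0.16 for Pecam1, 0.61 for Pdgfrb, 0.05 for Cspg4, 0.14 for Hgf, 0.12 for Vegfa, 0.52 for Hbegf, 0.22 for Nes, 0.34 for Gja4, 0.06 for Vtn, 0.30 for Sncg, 0.21 for Acta2, 0.13 for Col15a1, 0.14 for Lama4, 0.06 for Ifit3 and 0.14 for Hey1. The list means became 0.13 for pericyte, 0.43 for smooth muscle, 0.11 for fibro-adipogenic, -0.24 for lymphocyte, 0.05 for growth factor, 0.20 for receptor, 0.41 for fibrillar collagen, 0.27 for basement membrane, 0.32 for SRF and YAP, 0.22 for integrin, 0.36 for Notch, 0.07 for neurovascular and 0.06 for ion channel lists. With summed transcript counts Greb1l became -0.29 and Fgf2 0.17. Vegfa, at -0.01, became 0.01 with DESeq2 and with RLE, 0.04 unfiltered, 0.04 with protein-coding genes only and 0 without mitochondrial and ribosomal RNA genes. Leaving out libraries, Vegfa spanned -0.08 to 0.09, Hbegf -0.40 to 0.21, Il6 -0.03 to 1.07 and Pgf -0.10 to 0.87. At this depth and spread, 2-fold changes were mostly not detectable.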

Other observations

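The tests in this part that use the endothelial list score, and the counts over a list alone with a library left out, were chosen after the results were seen. Besides the genes above, the Wnt list held 2 members past the threshold adjusted over the list alone, the secreted inhibitor Sfrp2 (log2 fold change -1.74, SE 0.42) and the ligand Wnt5a (-2.27, SE 0.59). In the list of mesenchymal progenitor markers, Lif was higher and Klf4 and the chemokine Cxcl12 were lower, with Cxcl12 at 262 ± 78.1 against 645 ± 286 CPM (SD, n = 3). In the same libraries the mean endothelial marker level was lower, at 7.26 log2 CPM against 8.29 in sham. Neither list passed camera (adjusted p = 0.17 and 0.14), and 0 members of either passed over all genes. Without sham replicate 2, stimulated replicate 1 or stimulated replicate 2 both lists had 0 members past the threshold over the list alone; the 2 Wnt members also became 0 without stimulated replicate 3, and of the progenitor markers 1 higher and 4 lower passed without stimulated replicate 3, 2 and 5 without sham replicate 1, and 1 and 0 without sham replicate 3.

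With the endothelial list score as a covariate, genes of the metallothionein and glucocorticoid list had larger fold changes, none past the threshold over all genes: Mt1 2.64, Mt2 4.23, Zbtb16 2.68 and Fkbp5 2.30 on the log2 scale. The metallothionein and glucocorticoid list had a mean log2 difference of 1.08 there, and the chemokine list 0.91. The score itself separated the groups, at 6.99 to 7.58 against 7.6 to 9 log2 CPM. These values therefore cannot tell stimulation from the endothelial level.

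B cell transcripts were abundant in a sort that excluded CD45. Ighm stood at 711 ± 133 CPM (SD, n = 3) after stimulation and 596 ± 465 CPM (SD, n = 3) in sham, and Cd79a at 184 ± 13.7 and 171 ± 149 CPM (SD, n = 3).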
